A study of Homo sapiens with 24 samples.

How the data were processed

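The series measured polyadenylated RNA in K562 cells by paired-end, strand-specific RNA sequencing, per the labels' protocols. The cells carried a Cas9 without nuclease activity, fused to the KRAB repressor and induced with doxycycline for 24 hours, and a single sgRNA per culture. The library for each culture was made from 10000 lysed cells, per the labels' protocols. The design has 8 sgRNAs with 3 biological replicates each, which gives 24 libraries: 2 sgRNAs for the GATA1 transcription start site (GATA1TSS), 2 for eHDAC6 and 4 non-targeting controls (NC). Samples were grouped by these labels. The target coordinates of the sgRNAs are not given in the sources used here.

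The authors deposited a table of raw counts per gene symbol, whole numbers with 1 column per library, and a file of RefSeq gene models. The submitters' processing notes name the hg19 build and Bowtie2 2.1.0, TopHat2 2.0.8, Picard and SAMtools 0.1.19, with no role or order. The counting tool, whether a read pair counted once, and whether strand was used in counting are not given in the sources used here, so overlapping genes and antisense genes are reported as uncertain. The count table holds 21925 gene entries, of which 2226 have no count in any library, 160 share every value with another entry at 50 or more counts, and 21 carry a date in place of a symbol. The entries with dates hold 0.198% of the counts, were kept in the fits and are not named. Gene positions were read from the deposited gene models, which placed 21904 of the symbols, and are given 1-based on hg19.

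Total counts ran from 4290343 to 23205811 per library with a median of 13479000, and this depth sets the precision of low values. TMM scaling factors, which correct for the composition of each library, ran from 0.951 to 1.03. Levels are given as CPM, the deposited counts divided by the TMM-scaled total of their library and brought to a common scale, and the SD is that between libraries. Principal components were taken from log2 CPM (prior count 2) of the 2000 most variable genes.

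Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, estimated dispersions, quasi-likelihood fits and F tests). Genes were kept by edgeR's filter with sgRNA as the group (minimum count 10, minimum total count 15, proportion 0.7), which left 13147. The model had 1 coefficient per sgRNA over all 24 libraries. An element was compared with NC as the mean of its 2 sgRNAs minus the mean of the 4 NC sgRNAs, eHDAC6 with GATA1TSS in the same way, and the sgRNAs of an element with each other. The 4 NC sgRNAs were compared in 1 test with 3 contrasts. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. The error in this model is the spread between replicates of an sgRNA, and it holds no variation from sgRNA to sgRNA, which enters only in the element model and in the model of summed counts.

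Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on the edgeR fit, with adjusted p-values over the 21 lists, and again with an estimated correlation and with fry. The lists were globins, heme biosynthesis, erythroid membrane and blood groups, iron handling, erythroid regulators, progenitor regulators, megakaryocyte, myeloid and lymphocyte markers, fibroblast and epithelial markers, S phase, G2 and M phase, p53 targets, interferon response, integrated stress response, cholesterol biosynthesis, glycolysis, cytosolic ribosomal proteins, heat shock and chaperones, immediate early genes, and autophagy with mitochondrial clearance. Locus genes were those with a transcript start within 1 Mb of that of GATA1. K562 cells are of erythroid and megakaryocyte character, so the lineage lists hold genes that the cells express themselves.

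The tests, the gene lists, the alternatives other than 3 and the rule for naming genes were fixed before the data were examined. The rule named, for each element against NC, GATA1, HDAC6, the called locus genes, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM that changed the same way with both sgRNAs and in 6 of 6 libraries, and up to 4 called members per list with the largest changes. Between sgRNAs it named up to 5 genes with the smallest p and a mean of at least 5 CPM. The text takes its genes from those, and some of them are not reported here. Up to 8 rises and 8 falls called against each control subset were added after the data had been seen. Exons of KLF3, ARHGAP9, STEAP3, LST1, KRT8, CCDC22, PTPN22 and ATF5 overlap an antisense gene, those of P2RX5, S1PR3 and SPTB a gene on the same strand, and SSX3, CKMT1B and the ribosomal protein genes have close copies, so these values are uncertain in the same sense.

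The control libraries fell into 8 and 4, a split found in the data (principal component 1 of the NC libraries). It is used descriptively. Calls between the 8 and the 4 were not made. The 3 alternatives added after this was seen left out the 8, left out the 4, or entered the subset as a model term. The alternatives fixed in advance were RLE and upper quartile scaling, no filter, a minimum mean of 5 CPM (20 for the correlation), 1 coefficient per element, counts summed per sgRNA, the replicate number as a block, libraries thinned at random to the smallest total, only the libraries of the groups compared, DESeq2 1.42.0, glmTreat against a fold of 1.2, fry, an estimated correlation, a window of 100 kb, and each library and each sgRNA left out in turn.

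The responses to the elements were compared by overlap of calls and by the correlation and covariance of log2 fold changes across genes, with 20 simulations of unchanged groups against the same controls, and with the control sgRNAs split between the elements. Other groupings of the same libraries were refitted, up to 100 per comparison. The edgeR steps were tested on simulated counts with 200 changed genes. For GATA1TSS against NC 83% of the genes changed 1.5-fold and 98% of those changed 2-fold were called, with 10 unchanged genes among 191 calls. For eHDAC6 against NC these were 84% and 97%, with 5 unchanged among 186. For GATA1TSS against the 4 control libraries they were 80% and 94%, with 10 unchanged among 184. The simulated libraries shared the same mean levels apart from the changed genes, with no control subsets and no differences between sgRNAs. These shares therefore test the steps and do not give the share of false calls in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. XIST and genes of the Y chromosome are not reported.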

Results

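Polyadenylated RNA was sequenced on a strand-specific, paired-end protocol from K562 cells, a human erythroleukaemia line, that carried an inducible CRISPR interference (CRISPRi) system. In this system a Cas9 without nuclease activity, joined to the KRAB repressor domain, is brought to a chosen site by a single guide RNA (sgRNA). Doxycycline was given for 24 hours to induce it. The libraries came from 8 sgRNAs with 3 biological replicates each, 24 in all. Of these, 6 libraries carried 1 of 2 sgRNAs against the transcription start site of GATA1 (GATA1TSS), 6 carried 1 of 2 sgRNAs against eHDAC6, a putative enhancer of GATA1, and 12 carried 1 of 4 non-targeting control sgRNAs (NC). Total counts per library ran from 4290343 to 23205811, with a median of 13479000. The lowest total was that of GATA1TSS-Guide2 replicate 2, and the next lowest was 7327820 (NC-Guide1 replicate 1). Of 21925 gene entries in the count table, 13147 passed the filter on low counts and were tested.

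The 12 control libraries were not alike. On principal component 1 of the control libraries, which held 26.1% of their variance, 8 libraries (all of NC-Guide1 and NC-Guide2, and replicate 1 of NC-Guide3 and of NC-Guide4) stood apart from the other 4 (replicates 2 and 3 of NC-Guide3 and of NC-Guide4). Genes of the integrated stress response, globin genes and genes of the erythroid membrane were higher in the 8 than in the 4, by list medians of 0.86, 0.67 and 0.45 on the log2 scale. A line through the 2 subset means over 172 genes, scaled to put the 4 at 0 and the 8 at 1, placed the 12 targeted libraries between -0.184 and 0.103. The labels used here give no date, lane or library batch. Each comparison with NC is therefore given against all 12 control libraries, as laid down in advance, and again against the 4 control libraries alone, a choice made after the data had been seen.

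**Figure D1:**
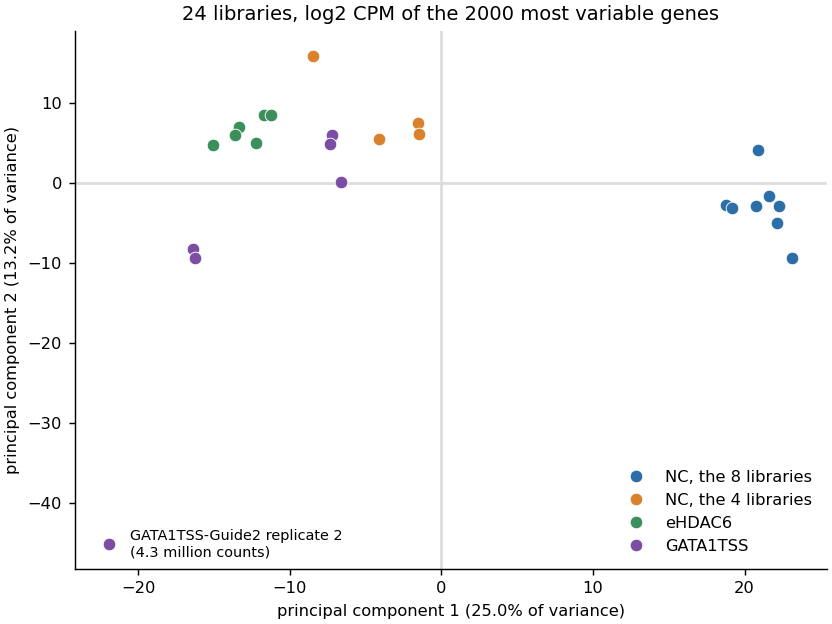
Principal components 1 (25.0% of variance) and 2 (13.2%) of log2 CPM (counts scaled to a common library total) in all 24 libraries, each point a library coloured by targeted element and by control subset. The 8 control libraries lie apart from the other 4, and GATA1TSS-Guide2 replicate 2, the library with the lowest total, lies far from the rest on component 2.

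GATA1, the zinc-finger transcription factor that directs erythroid and megakaryocyte gene expression, was measured in each library to check the labels. The gene lies at position 48644982 to 48652717 on the plus strand of chromosome X in hg19 and has 6 exons. It stood at 363 ± 28.9 CPM (SD, n = 12) in the control libraries, at 254 ± 8.72 (n = 6) with the eHDAC6 sgRNAs and at 84.8 ± 37.1 (n = 6) with the GATA1TSS sgRNAs. These levels were 69.9% and 23.4% of the control mean. Every targeted library lay below every control library, whose lowest value was 281 CPM (NC-Guide2 replicate 1). The 8 and the 4 control libraries had like GATA1 levels, 361 ± 35.2 (n = 8) and 366 ± 12.8 CPM (n = 4).

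The question put by the series was whether repression of the putative enhancer lowers GATA1, and how this compares with repression of its start site. GATA1 fell by 0.52 on the log2 scale with eHDAC6 (SE 0.07, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.52e-06), in 6 of 6 libraries. With GATA1TSS it fell by 2.19 (SE 0.07, edgeR adjusted p = 2.81e-17), in 6 of 6 libraries. The direct test of the difference gave a log2 difference of 1.67 (SE 0.08, edgeR adjusted p = 1.13e-13). Both eHDAC6 sgRNAs gave near-equal levels, 247 ± 5.29 and 260 ± 6.16 CPM (n = 3 each). The GATA1TSS sgRNAs differed, with 117 ± 18.0 CPM for GATA1TSS-Guide1 and 53.1 ± 9.67 CPM for GATA1TSS-Guide2, a log2 difference of 1.10 (SE 0.11, edgeR adjusted p = 2.59e-06). Against the 4 control libraries the GATA1 changes were -0.53 with eHDAC6 and -2.20 with GATA1TSS. In a model that summed the counts of each sgRNA, so that the error was that between sgRNAs, the eHDAC6 change was -0.51 and no longer passed (edgeR adjusted p = 0.149), and neither did the difference between the elements (1.54, edgeR adjusted p = 0.153). That error was pooled over all sgRNAs and so holds the difference between the GATA1TSS sgRNAs. The lost call therefore does not show that the eHDAC6 sgRNAs disagreed.

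**Figure D2:**
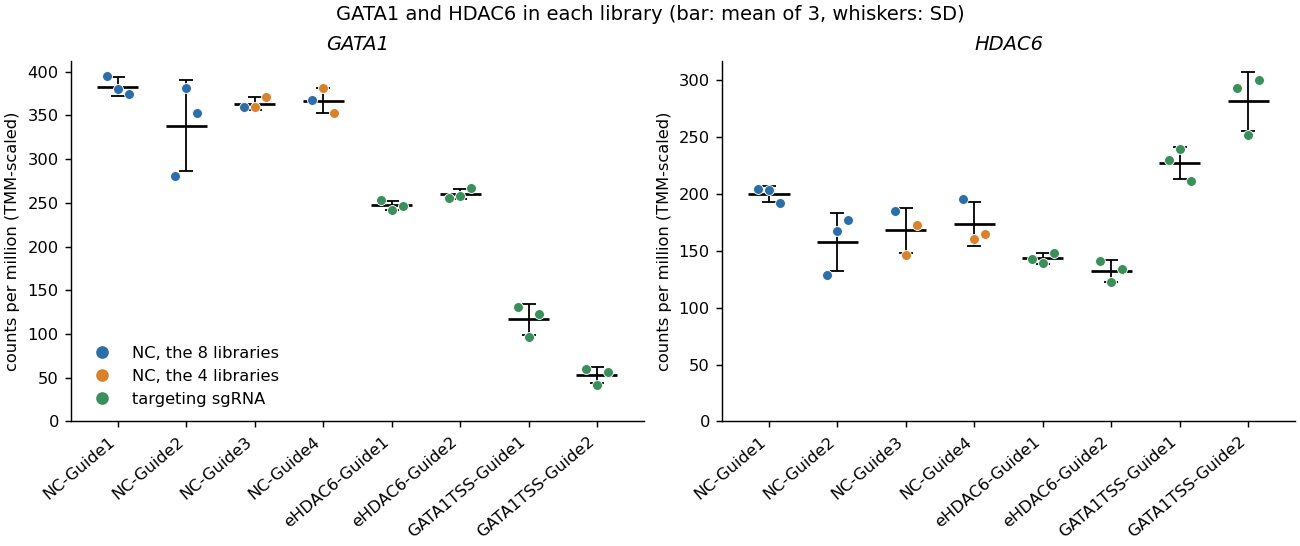
GATA1 and HDAC6 in CPM (TMM-scaled) for each of the 8 sgRNAs, with a point per library, a bar at the mean of 3 and whiskers of 1 SD. GATA1 lies lowest with GATA1TSS-Guide2 (53.1) and GATA1TSS-Guide1 (117) and between these and the controls with both eHDAC6 sgRNAs (247 and 260), while HDAC6 lies highest with the GATA1TSS sgRNAs.

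HDAC6, which encodes a cytoplasmic deacetylase of tubulin and gives the element its name, starts 15.5 kb from GATA1 (chromosome X, 48660487 to 48683380). It moved in opposite directions with the 2 elements. It rose with GATA1TSS, from 175 ± 23.1 CPM (n = 12) to 254 ± 35.2 (n = 6), a log2 change of 0.54 (SE 0.06, edgeR adjusted p = 4.91e-07) in 6 of 6 libraries, and by 0.65 against the 4 control libraries. It fell by 0.34 with eHDAC6 (SE 0.07, edgeR adjusted p = 4.33e-04), to 138 ± 9.05 CPM (n = 6), in 6 of 6 libraries. The fall with eHDAC6 did not pass against the 4 control libraries (-0.23, edgeR adjusted p = 0.0776), with the control subset as a model term (-0.18, adjusted p = 0.343) or with counts summed per sgRNA (adjusted p = 0.108). The direct difference between the elements was -0.88 (SE 0.08, edgeR adjusted p = 5.33e-08).

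Of 74 genes with a transcript start within 1 Mb of that of GATA1, 69 were tested, 22 of them copies of the GAGE family. A change in these copies may be counted many times with either element. Of all 13147 genes tested, 1775 rose and 1805 fell with GATA1TSS, and 2077 rose and 2011 fell with eHDAC6. Calls at the locus are to be read beside these, and an excess there was not tested. With GATA1TSS 14 rose and 13 fell (adjusted over the list alone, 19 and 27), and against the 4 control libraries 9 rose and 3 fell. WAS, a regulator of the actin cytoskeleton in blood cells, rose by 0.90 (SE 0.08; 0.56 against the 4), the cancer-testis gene SSX3 by 0.55 (0.47) and the transcription factor gene TFE3 by 0.41 (0.25), while CCDC22 fell by 0.38 (0.31). SSX3 did not pass without GATA1TSS-Guide2 (0.20). The kinase gene PIM2 stood at 0.21 (0.37; 5 of 6 libraries) with an edgeR adjusted p of 0.0493, and this call was lost in 6 of 10 alternative fits and in 19 of 32 fits with a library or sgRNA left out. With eHDAC6 10 genes rose and 28 fell (adjusted over the list alone, 11 and 30), but 22 of the 28 were copies of the GAGE family, whose reads cannot be told apart with certainty, and against the 4 control libraries 3 rose and 1 fell. WAS rose by 0.69 with eHDAC6 (0.35 against the 4) and SSX3 by 0.60 (0.52). PLP2 and PRICKLE3, which overlap on opposite strands, rose by 0.55 and 0.46 with eHDAC6 and by 0.42 and 0.34 with GATA1TSS, and did not pass against the 4. Among the 6 genes within 100 kb, the calls with eHDAC6 were falls of GATA1, of HDAC6 and of GLOD5 (-1.38, SE 0.28), the last at a mean of 1.89 CPM and not called against the 4 (-0.54). With GATA1TSS they were GATA1, HDAC6 and 2 weakly expressed genes, ERAS (0.606 CPM with GATA1TSS) and PCSK1N (1.21 CPM), the latter not called without GATA1TSS-Guide2 (0.40). Against the 4, ERAS, which had 0 CPM in each of them, was called higher with both elements, and GLOD5 and PCSK1N higher with GATA1TSS.

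**Figure D3:**
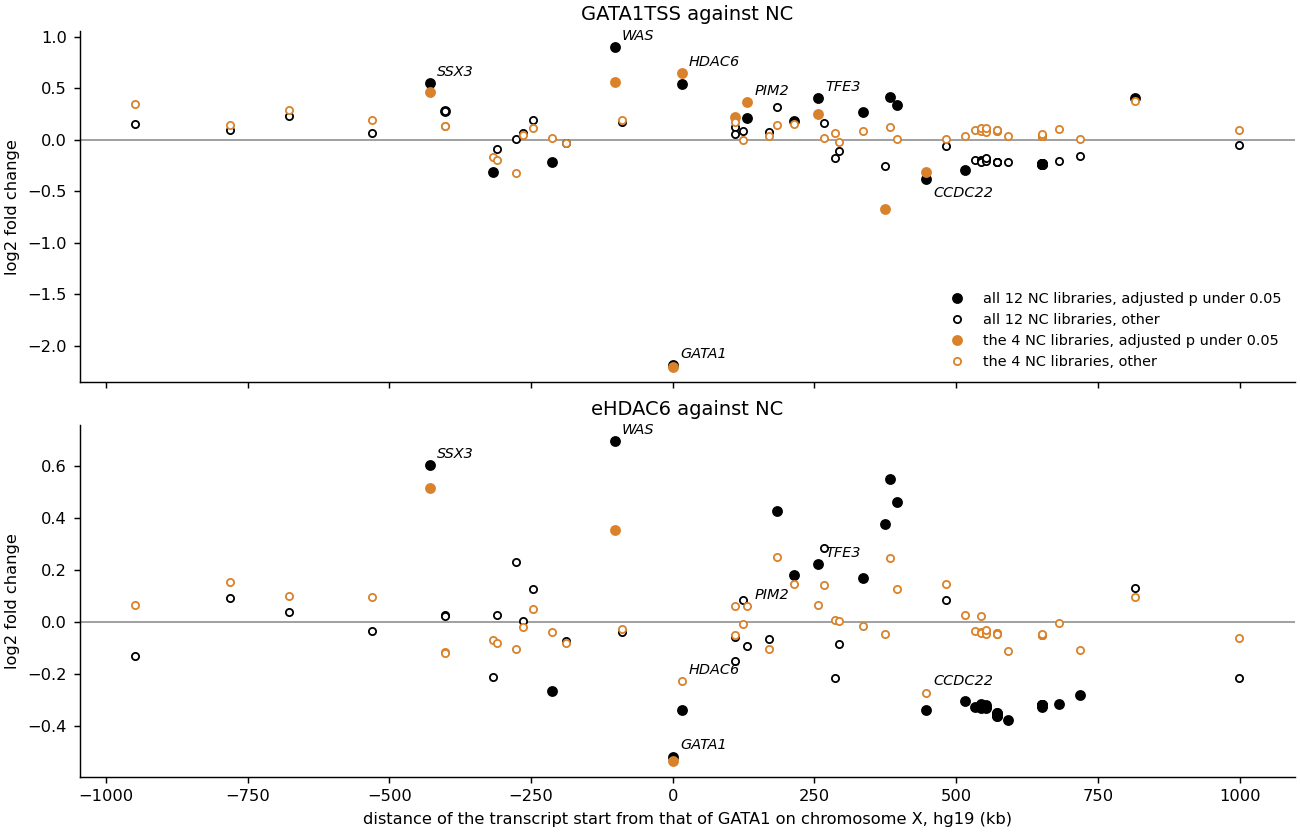
Log2 fold changes of the tested genes with a mean of at least 5 CPM within 1 Mb of GATA1 on chromosome X (hg19) by the distance of their transcript starts in kb, for both elements, against all 12 control libraries and against the 4. Filled points passed an adjusted p of 0.05, and the run of falls with eHDAC6 between 515 and 719 kb is the GAGE family.

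Beyond the locus, KLF1, the erythroid Krüppel-like factor, fell with GATA1TSS by 0.96 (SE 0.06; 0.85 against the 4 control libraries), EPOR, the erythropoietin receptor, by 0.66 (0.57), LDB1, which forms a complex with GATA1, by 0.47 (0.49; not past the threshold without GATA1TSS-Guide2, -0.23), KLF3 by 0.41 (0.32) and MYC by 0.73 (0.61). Among called genes with a mean of at least 5 CPM that moved the same way in 6 of 6 libraries, those with the largest falls included asparagine synthetase ASNS (-2.19, SE 0.23), the serine synthesis enzymes PSAT1 (-2.18) and PHGDH (-2.05), CTH of cysteine synthesis (-1.76), the alanine aminotransferase GPT2 (-1.95), the glutathione-degrading enzyme CHAC1 (-2.29), the mitochondrial folate enzyme ALDH1L2 (-2.22) and INHBE (-1.99). Against the 4 control libraries the falls of these 8 genes were smaller, from 0.62 (CTH) to 1.03 (CHAC1), and each passed. TF, transferrin, fell by 2.48 against all controls (SE 0.45) but was level with the 4 (0.05). The largest rises among such genes were those of the imprinted RNA H19 (1.98, SE 0.20) with its antisense partner HOTS (2.00), whose reads cannot be told apart from it, the calcium-binding protein calbindin CALB1 (1.96, SE 0.13), EVI2B (1.66), MMRN2 (1.57), the urokinase gene PLAU with its antisense gene C10orf55 (both 1.55), TRIM22 (1.52), ARHGAP9 (1.47) and SLAMF6 (1.46), and against the 4 they ranged from 0.62 (C10orf55) to 2.22 (CALB1). Each of these genes moved the same way in 6 of 6 libraries. H19 differed between the sgRNAs, with 60.3 CPM for GATA1TSS-Guide1 and 209.5 CPM for GATA1TSS-Guide2. Without GATA1TSS-Guide2, against all controls, smaller rises passed for HOTS (1.15), CALB1 (1.26), EVI2B (1.11), MMRN2 (0.85), TRIM22 (0.95), ARHGAP9 (0.98) and SLAMF6 (0.76). Without GATA1TSS-Guide1 these were 2.85, 2.67, 2.22, 2.30, 2.09, 1.97 and 2.17. PLAU and C10orf55 moved most without a control sgRNA instead. Among these rises, only CALB1 and ARHGAP9 stood above all of the 4 control libraries in each GATA1TSS-Guide1 library.

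In all, 1775 genes rose and 1805 fell with GATA1TSS (edgeR, 3580 at an adjusted p under 0.05), and against the 4 control libraries 635 rose and 708 fell. Of the 3580, 1031 were called in the same direction against the 4 and 4 in the opposite direction. Against each subset of the control libraries taken alone, 441 genes rose and 451 fell both times, while 49 were called in opposite directions. The count was 1625 without GATA1TSS-Guide2 and 632 with counts summed per sgRNA. Among genes called the same way against each subset, chosen after the data had been seen, were the rises of the sphingosine receptor S1PR3 (1.25, and 1.26 against the 4), of BTBD19 (1.41 and 1.22) and of LINC00891 (1.27 and 1.41), a gene counted identically to LOC100132741, and the fall of the netrin receptor UNC5B (-1.46 and -1.03).

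**Figure D4:**
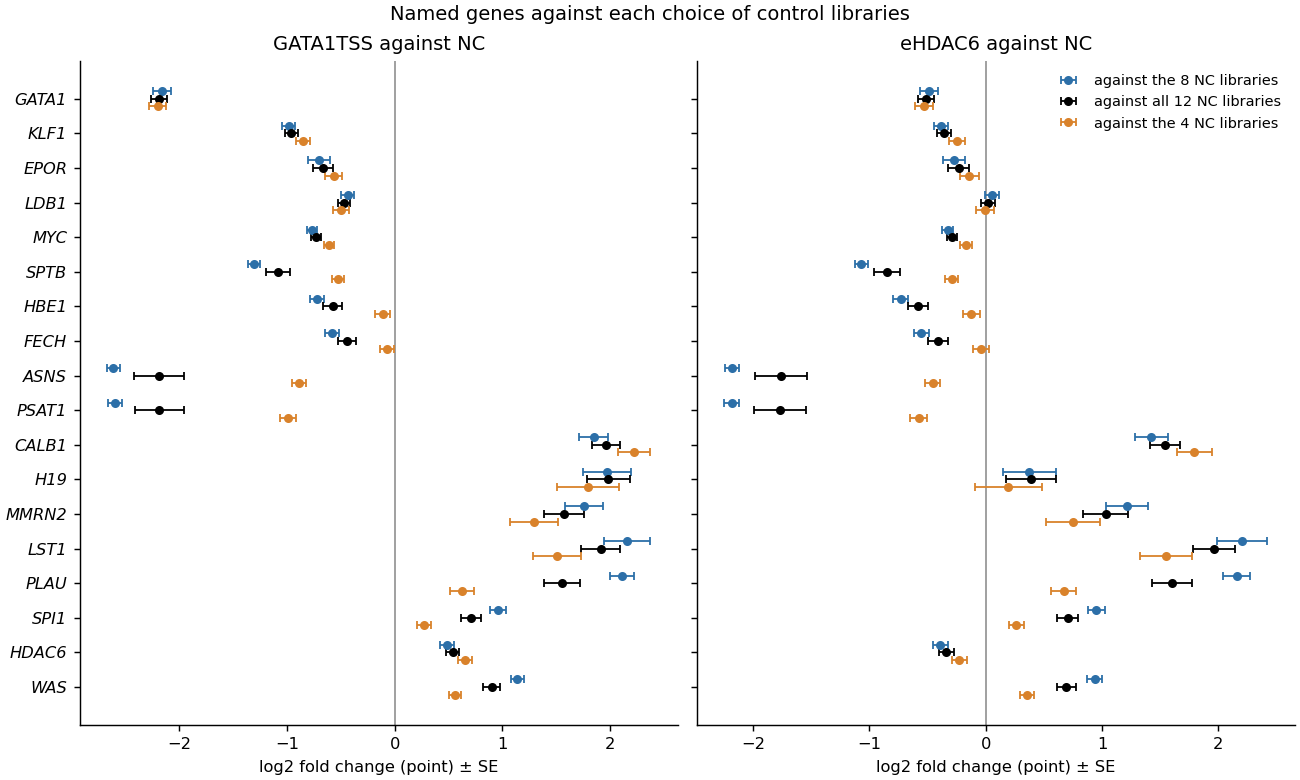
Log2 fold changes with their standard errors for a selection of the named genes, with GATA1TSS and with eHDAC6, against all 12 control libraries, against the 4 and against the 8. The points for CALB1 and GATA1 lie close together whichever control libraries are used, while those for ASNS and PSAT1 lie far apart.

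The 21 gene lists fixed before were tested with camera, which compares a list with all other genes. Of the 17 measured genes of the integrated stress response, 16 fell with GATA1TSS (16 adjusted over the list alone), with a median log2 change of -1.13 (camera adjusted p = 1.39e-24; adjusted p = 0.0259 with an estimated correlation). The median was -0.60 against the 4 control libraries, again with 16 of 17 called lower (camera adjusted p = 2.23e-34; adjusted p = 0.00329 with an estimated correlation). Of 14 erythroid regulators 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 5.04e-07, and 0.0233 as adjusted p with an estimated correlation), and 6 fell against the 4. Of 11 iron handling genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00158, adjusted p = 0.0233 with an estimated correlation), among them BLVRB, a biliverdin reductase (-0.42), STEAP3, a ferric reductase (-0.63), and the transferrin receptor TFR2 (-0.37), and 4 fell against the 4. Without GATA1TSS-Guide2 these 3 genes did not pass (BLVRB -0.16, STEAP3 -0.36 and TFR2 -0.24). Of 37 cytosolic ribosomal protein genes 30 fell (32 adjusted over the list alone), by a median of -0.21, for example RPS13 (-0.31) and RPS18 (-0.29), with camera adjusted p = 1.87e-11 (adjusted p = 0.226 with an estimated correlation). Against the 4, 23 fell, with camera adjusted p = 3.34e-15 (adjusted p = 0.208 with an estimated correlation).

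Markers of terminal erythroid cells moved with the control subsets. With GATA1TSS, 9 of 10 globin and globin chaperone genes fell (9 adjusted over the list alone), among them HBE1 (-0.57), HBZ (-0.66) and AHSP (-1.07), as did 12 of 21 genes of the erythroid membrane (14), among them SPTB (-1.08), and 9 of 12 heme synthesis genes (10, with 1 rise), among them FECH (-0.44). The camera adjusted p-values were 5.91e-06, 1.58e-07 and 1.59e-04, and each was 0.226 as an adjusted p with an estimated correlation. Against the 4 control libraries the medians were -0.05 (globins), -0.02 (membrane) and -0.11 (heme), with camera adjusted p = 0.572, 0.237 and 0.0440, the last of which was 0.525 with an estimated correlation. SPTB still fell, by 0.52, whereas HBZ stood at 0.12, HBE1 at -0.11, AHSP at -0.15 and FECH at -0.07, none of which passed. HBZ was below the mean of all controls in 5 of 6 libraries and the other genes just named in 6 of 6. Without GATA1TSS-Guide2, against all controls, HBE1 (-0.33), HBZ (-0.48) and FECH (-0.30) did not pass.

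Markers of other blood lineages and of growth responses rose in part with GATA1TSS. Of 10 myeloid markers 3 rose (3 adjusted over the list alone; camera adjusted p = 0.00178, adjusted p = 0.0594 with an estimated correlation), among them LST1 (1.91; 1.51 against the 4 control libraries) and the signalling adaptor TYROBP (0.92; 0.46). LST1 was weakly expressed and rose most with GATA1TSS-Guide2. It stood at 1.61 to 3.55 CPM in the GATA1TSS-Guide1 libraries and at 9.56 to 10.5 CPM in those of GATA1TSS-Guide2. NC-Guide3 replicate 2, among the 4, had 1.49 CPM. The myeloid regulator SPI1 rose by 0.71 (0.27). Of 17 glycolysis genes 6 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00813, adjusted p = 0.403 with an estimated correlation), with rises of the pyruvate kinase PKM (0.64; 0.30) and the glucose transporter SLC2A3 (0.55; 0.34), and the list did not pass against the 4 (camera adjusted p = 0.0708). Of 15 immediate early genes 8 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00920, adjusted p = 0.233 with an estimated correlation), with rises of IER5 (0.65; 0.47) and of EGR1 (0.55; 1.01), the latter in 5 of 6 libraries. The other 11 lists were not called. Among their members, the platelet collagen receptor GP6 rose by 0.99 (0.75), PLEK by 2.17 (3.00) from 0.599 CPM in the controls, the keratin KRT8 by 0.56 (0.47) and COL1A1 by 0.67 (1.49), COL1A1 in 4 of 6 libraries and PLEK in 5 of 6. Without GATA1TSS-Guide2 the call was lost for PLEK (0.74, edgeR adjusted p = 0.232; 1.01 CPM with GATA1TSS-Guide1 against 7.60 with GATA1TSS-Guide2), COL1A1 (0.22, 0.610), EGR1 (0.25, 0.554) and TYROBP (0.39, 0.208). That of COL1A1 was also lost without GATA1TSS-Guide1 replicate 2 (0.49, 0.0685), and that of EGR1, at an adjusted p of 0.0325, in 4 of 10 alternative fits and 9 of 32 with a library or sgRNA left out.

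**Figure D5:**
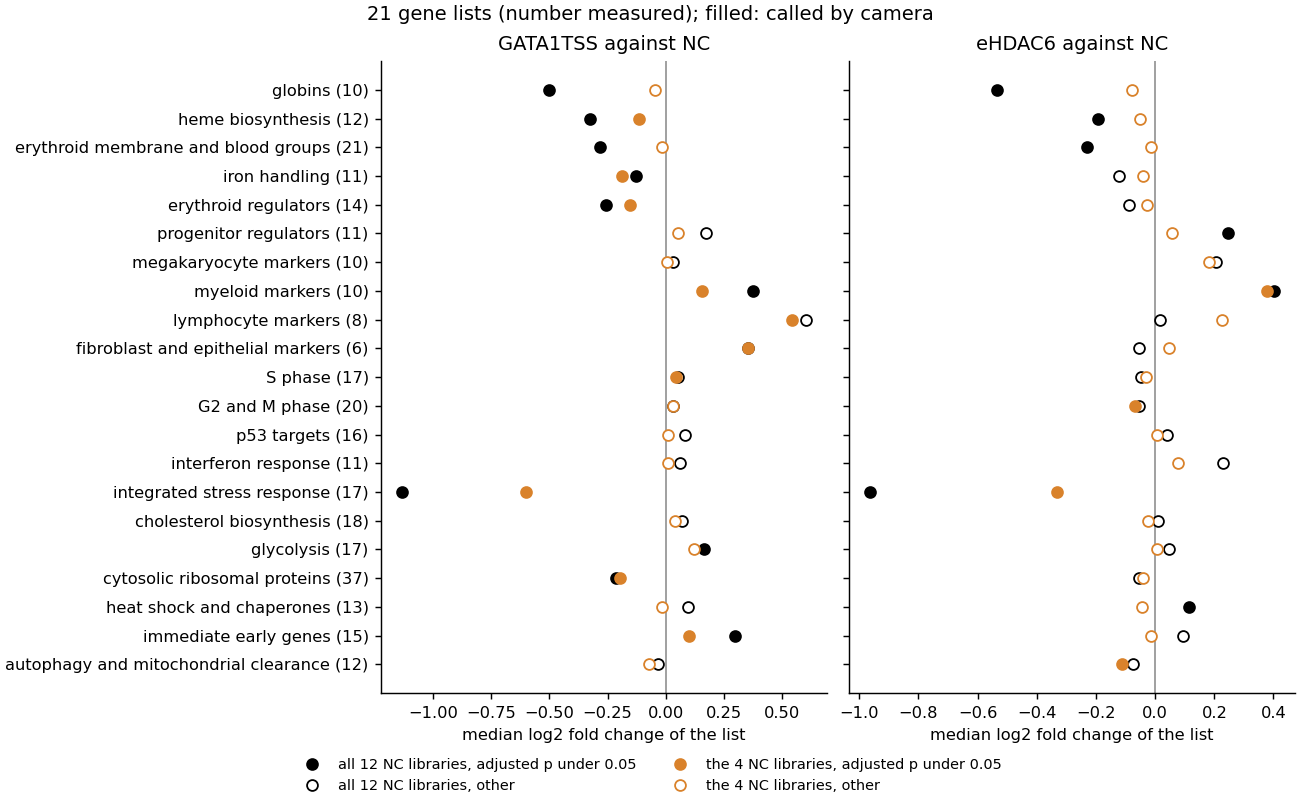
Median log2 fold change of each of the 21 gene lists (in brackets, the genes measured with all 12 control libraries) with GATA1TSS and with eHDAC6, against all 12 control libraries and against the 4. Filled points were called by camera at an adjusted p of 0.05, and the integrated stress response lies lowest in both panels with either choice of controls.

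The camera adjusted p-values of the uncalled lists with GATA1TSS were 0.0969 for progenitor regulators (5 of 11 rose, 1 fell), 0.256 for megakaryocyte markers (2 of 10 rose, 3 fell), 0.171 for lymphocyte markers (3 of 8 rose, 1 fell), 0.0990 for fibroblast and epithelial markers (4 of 6 rose, 1 fell), 0.102 for S phase (6 of 17 rose, 1 fell) and 0.307 for G2 and M phase genes (2 of 20 rose, 1 fell). They were 0.966 for p53 targets (3 of 16 rose, 3 fell, and the median of 0.08 and the test differed in sign), 0.314 for the interferon response (2 of 11 rose), 0.306 for cholesterol synthesis (2 of 18 rose), 0.0517 for heat shock and chaperone genes (6 of 13 rose) and 0.102 for autophagy genes (4 of 12 fell). Against the 4 control libraries the lymphocyte (0.0406), fibroblast and epithelial (0.00260) and S phase (0.0185) lists were called higher, and with an estimated correlation none of these passed (adjusted p = 0.130, 0.130 and 0.525).

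With the eHDAC6 sgRNAs PSAT1 fell by 1.77 (SE 0.22; 0.58 against the 4 control libraries) and ASNS by 1.76 (0.46), both past the threshold either way. SLC7A11, the cystine transporter, fell by 1.59 (0.75) together with its overlapping antisense gene SLC7A11-AS1 (-1.52; -0.70), TAC3, a neurokinin precursor, by 1.59 (0.99) and the apelin receptor APLNR by 1.10 (0.66). CALB1 rose by 1.54 (SE 0.13; 1.79), GPR85 by 1.43 (0.97), ARHGAP9 by 1.38 (0.70), P2RX5 by 1.29 (0.82), EVI2B by 1.46 (0.75), PLAU by 1.60 (0.67) and C10orf55 by 1.61 (0.67), each past the threshold either way and in 6 of 6 libraries. KLF1 fell by 0.36 (SE 0.06, edgeR adjusted p = 5.27e-05), and stood at -0.25 against the 4 (adjusted p = 0.0564). Further genes among those with the largest changes, at a mean of at least 5 CPM, did not pass against the 4, namely SIGLEC6 (1.59; 0.32), FYB (1.53; 0.43), ANKRD33 (1.28; 0.03), TF (-2.49; 0.05), LINC01028 (-2.21; -1.36), FLT1 (-2.07; -0.37), ALDH1L2 (-1.84; -0.39), INHBE (-1.78; -0.41), CHAC1 (-1.74; -0.48) and KCNJ16 (-1.67; -0.93).

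In all, 2077 genes rose and 2011 fell with eHDAC6 (edgeR, 4088 called), but against the 4 control libraries 118 rose and 77 fell. Of the 4088, 176 were called in the same direction against the 4 and 0 in the opposite direction. With the control subset as a model term the count was 109, and with counts summed per sgRNA it was 280. Without eHDAC6-Guide2 it was 1993, without eHDAC6-Guide1 2219 and without NC-Guide2 2612. Genes called the same way against each subset, chosen after the data had been seen, included COL9A2 (1.14; 1.05 against the 4), the axon guidance receptor ROBO2 (1.04; 1.17), the phosphatase PTPN22 (0.87; 0.97), S1PR3 (0.88; 0.89) and BTBD19 (1.10; 0.91).

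By list, 15 of 17 genes of the integrated stress response fell with eHDAC6 (16 adjusted over the list alone), by a median of -0.97 (camera adjusted p = 3.72e-17; adjusted p = 0.124 with an estimated correlation), and 7 fell against the 4 control libraries, where the median was -0.33 (camera adjusted p = 6.72e-21; adjusted p = 0.0215 with an estimated correlation). Of 10 myeloid markers 5 rose (5 adjusted over the list alone; camera adjusted p = 4.74e-04, adjusted p = 0.0715 with an estimated correlation), with LST1 at 1.96 (1.55 against the 4), TYROBP at 0.97 (0.51, not past the threshold) and the sialic acid lectin CD33 at 0.73 (0.26, not past it). The myeloid list was also called against the 4 (camera adjusted p = 4.99e-05, and 0.0225 as adjusted p with an estimated correlation). Globin genes (9 of 10, and 9 adjusted over the list alone), erythroid membrane genes (12 of 21, and 14) and heme synthesis genes (10 of 12 with 2 rises, and 10 and 2) fell against all controls, for example HBE1 (-0.58), AHSP (-1.14), SPTB (-0.85), FECH (-0.41) and the erythroid aminolevulinate synthase ALAS2 (-0.37). Their camera adjusted p-values were 5.78e-07, 5.78e-07 and 0.0109, with an estimated correlation adjusted p = 0.230, 0.230 and 0.339, and against the 4 control libraries 0.171, 0.490 and 0.422. Of the genes just named, SPTB alone passed against the 4 (-0.29), and FECH (-0.29) and ALAS2 (-0.25) did not pass against all controls without eHDAC6-Guide1.

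Of 11 progenitor regulators 6 rose and 1 fell with eHDAC6 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0319, adjusted p = 0.325 with an estimated correlation), with SPI1 at 0.70 (0.26 against the 4 control libraries) and GATA2, a GATA factor of progenitor cells, at 0.38 (0.05, not past the threshold). Of 13 heat shock and chaperone genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0334, adjusted p = 0.427 with an estimated correlation), with HSPB1 at 0.49 (0.08) and CALR at 0.32 (0.10), neither past the threshold against the 4. Both lists were uncalled against the 4 (camera adjusted p = 0.370 and 0.697), where the G2 and M phase list (0.0400; adjusted p = 0.690 with an estimated correlation) and the autophagy list (0.0167; adjusted p = 0.0663) were called lower. Of the autophagy list, FOXO3 (-0.39; -0.19 against the 4) and MAP1LC3B (-0.32; -0.14) fell against all controls, neither past the threshold against the 4. IER5 of the immediate early list rose by 0.44 (0.25). The camera adjusted p-values of the other lists against all controls were 0.0807 for iron handling (1 of 11 rose, 5 fell), 0.0538 for erythroid regulators (1 of 14 rose, 6 fell), 0.239 for megakaryocyte (3 of 10 rose, 1 fell), 0.744 for lymphocyte (1 of 8 rose) and 0.970 for fibroblast and epithelial markers (1 of 6 rose). They were 0.373 for S phase (2 of 17 rose, 5 fell), 0.227 for G2 and M phase (1 of 20 rose, 5 fell), 0.670 for p53 targets (3 of 16 rose, 1 fell), 0.119 for the interferon response (4 of 11 rose), 0.970 for cholesterol synthesis (4 of 18 rose, 3 fell, and the median and the mean differed in sign), 0.373 for glycolysis (3 of 17 rose, 2 fell), 0.119 for ribosomal proteins (2 of 37 fell), 0.373 for immediate early (4 of 15 rose, 2 fell) and 0.0986 for autophagy genes (2 of 12 fell).

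Both responses overlapped. With both elements 1214 genes rose and 1142 fell, where independent lists of these sizes would share 280 and 276, and 2 genes moved in opposite directions. Against the 4 control libraries the overlaps were 96 and 68, where independent lists would share 5.71 and 4.15. Both comparisons share their control libraries. Simulated unchanged groups gave a correlation of fold changes of 0.344 across genes, against 0.773 observed, and a covariance of 0.00844, against 0.0962 observed. The simulated groups did not hold the control subsets, and all targeted libraries lay near the 4, so the excess against all controls cannot be set apart from that structure. Against the 4 the observed correlation was 0.679 with a simulated 0.622, and the covariance was 0.0569 with a simulated 0.0228. The share of genes with the same sign was 78.5% against all controls, with a simulated 60.9%, but 70.4% against the 4, no higher than the simulated 70.7%. With different control sgRNAs for each element, the correlation averaged 0.591 over 6 splits of the control sgRNAs (0.493 to 0.667), and 0.249 over the 2 splits that the 4 control libraries allowed (0.170 to 0.329). Every control sgRNA had libraries among the 8, so the average of 0.591 cannot be set apart from the control subsets either. These correlations run across genes, which are not independent replicates.

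The direct comparison of eHDAC6 with GATA1TSS called 201 genes, 115 higher and 86 lower with eHDAC6. The control libraries cancel from its fold changes but still enter its error, with the difference between the control subsets in NC-Guide3 and NC-Guide4. GATA1 (1.67), KLF1 (0.60, SE 0.07), LDB1 (0.49), MYC (0.44), EPOR (0.43) and UNC5B (1.07) were higher with eHDAC6, and HDAC6 (-0.88), H19 (-1.60) and LINC00891 (-0.99) were lower. The count rose to 670 in a fit of these 12 libraries alone and fell to 14 with 1 coefficient per element. It was 4 without GATA1TSS-Guide2, where of the genes just named GATA1 and HDAC6 passed, and 915 without GATA1TSS-Guide1, and leaving out a single library took it as low as 72 (without GATA1TSS-Guide1 replicate 2) and as high as 361 (without NC-Guide3 replicate 1).

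Between the GATA1TSS sgRNAs, 224 genes were higher with GATA1TSS-Guide1 and 233 higher with GATA1TSS-Guide2 (edgeR, 457 called). Besides GATA1, KLF1 was higher with GATA1TSS-Guide1 (0.90, SE 0.09), as was the progesterone receptor gene PGR (1.18, SE 0.13). ZBTB1, a zinc-finger gene on chromosome 14, was lower with it (-1.43, SE 0.14), as was LOC102723809 (-1.27), whose exons overlap those of ZBTB1 on the other strand. ZBTB1 stood at 8.01 CPM with GATA1TSS-Guide1, at 22.1 CPM with GATA1TSS-Guide2 and at 21.4 CPM in the controls. The count was 275 without GATA1TSS-Guide2 replicate 2, the library with the lowest total, and 178 without GATA1TSS-Guide1 replicate 1.

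Between the eHDAC6 sgRNAs, 2 genes were called, with 477 at an unadjusted p under 0.05. SLC4A1, the band 3 anion exchanger of red cells, was lower with eHDAC6-Guide1 (32.5 CPM against 82.6; log2 difference -1.34, SE 0.20, edgeR adjusted p = 0.00434), as was the water channel gene AQP1 (44.7 CPM against 71.8; -0.68, SE 0.12, edgeR adjusted p = 0.0267). The next genes by p-value, CA1 (-0.62), SLC16A9 (0.57) and CKMT1B (-0.69), did not pass. In a fit of the 6 eHDAC6 libraries alone 73 genes were called, and without eHDAC6-Guide1 replicate 2 or 3 0 genes were (edgeR, 414 and 368 at an unadjusted p under 0.05).

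Among the 4 control sgRNAs, which have no target, 1618 genes differed (edgeR, 1 test of 3 contrasts). FAM178B was highest with NC-Guide1 (744 CPM, against 337 to 423 with the other 3 sgRNAs), as were the metallothionein MT2A (38.0 CPM against 12.1 to 14.3), S100P (15.8 against 6.59 to 7.34) and the stress-induced factor ATF5 (455 against 151 to 189). The small nucleolar RNA host gene SNHG8 was lowest with NC-Guide2 (41.9 CPM against 62.3 to 68.5). Within the 4 control libraries, which hold 2 replicates of NC-Guide3 and 2 of NC-Guide4, 0 genes were called by edgeR, with 825 at an unadjusted p under 0.05, and no other tool was run on them alone. The count was 14 in a fit of the 12 control libraries alone, 2735 with DESeq2, 224 without NC-Guide2 and 3249 without NC-Guide3 replicate 1.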

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

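The tests below were chosen after the results were seen, except the depth test of the control subsets, the test of a graded response behind the difference between the GATA1TSS sgRNAs, and the splits without the 8 control libraries.

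A direct test of the difference between the responses to eHDAC6 and to GATA1TSS passed for 25 of the genes named. By log2 difference, with the edgeR adjusted p in brackets, genes higher with eHDAC6 were GATA1 1.67 (1.13e-13), UNC5B 1.07 (0.00819), ZBTB1 0.68 (3.33e-04), KLF1 0.60 (6.44e-06), LOC102723809 0.55 (0.00430), LDB1 0.49 (1.69e-04), MYC 0.44 (1.57e-05), EPOR 0.43 (0.0281), AQP1 0.42 (0.00875), PGR 0.41 (0.0146), CALR 0.32 (0.0269), RPS13 0.26 (0.0158) and RPS18 0.23 (0.0332). Genes lower with eHDAC6 were FLT1 -1.91 (0.0269), HOTS -1.64 (1.93e-04), H19 -1.60 (5.01e-04), GLOD5 -1.54 (0.00742), COL1A1 -1.03 (0.0189), LINC00891 -0.99 (4.93e-05), EGR1 -0.91 (0.0384), HDAC6 -0.88 (5.33e-08), MT2A -0.85 (0.0121), GP6 -0.55 (9.81e-04), KRT8 -0.46 (0.00591) and SLC2A3 -0.32 (0.0387). The error in this test is that between replicates of an sgRNA, and with counts summed per sgRNA 0 genes passed (edgeR, 568 at an unadjusted p under 0.05; DESeq2, on the libraries, called 394). Without GATA1TSS-Guide2 21 of the 25 no longer passed, and those that did were GATA1, HDAC6, LOC102723809 and ZBTB1. For 9 genes (RPS18, EPOR, COL1A1, SLC2A3, EGR1, FLT1, CALR, PGR and RPS13) leaving out a single library ended the call. ZBTB1, LOC102723809, PGR and AQP1 changed sign without 1 of the GATA1TSS sgRNAs.

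The control libraries fell into 8 and 4. An effect of single control sgRNAs is excluded as the whole cause, since 2 of them, NC-Guide3 and NC-Guide4, had libraries on both sides. For depth, the gap between the subsets, on a line with their means at 0 and 1, was 0.906 with libraries thinned to the smallest total and 0.904 before. This test cannot exclude depth, since the genes of the line, chosen anew, were picked by their difference between these same subsets. Total counts argue against depth as the whole cause: those of the 4 (13407605 to 15629571) lay within those of the 8 (7327820 to 16267886). Targeted libraries under a control name are excluded for the 4, since their lowest GATA1 level was 352 CPM, above the highest targeted level of 267 CPM. A difference in culture or library preparation may be the source and stays open, since the labels used here name no such batch, and no biological explanation was tested.

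HDAC6 was higher with GATA1TSS. Greater depth of these libraries is excluded, since the change was 0.54 (edgeR adjusted p = 4.24e-07) with all libraries thinned to the smallest total. A graded response to the fall of GATA1 may account for it, since HDAC6 was lower with GATA1TSS-Guide1, which left more GATA1, by -0.31 on the log2 scale (SE 0.10), but this difference did not pass (edgeR adjusted p = 0.0977). With eHDAC6 GATA1 fell too (-0.52), but HDAC6 did not rise (-0.34, and -0.23 against the 4). This cannot decide it, since GATA1 fell less there than with GATA1TSS. An effect of eHDAC6 repression on HDAC6 apart from GATA1 was not tested. A rise of the genes around GATA1 stays open as well, since the mean log2 change of the 5 nearest other genes with a mean of at least 5 CPM (GLOD5, ERAS and PCSK1N lie nearer, below it) against the 4 control libraries, 0.23, lay at percentile 98.1 of 10000 runs of 5 neighbouring genes (9923 on a single chromosome), although WAS (0.56) carried much of it and SLC35A2 was level (2.82e-04). Both explanations were set up on the data that gave the pattern, and neither was told from the other.

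The GATA1TSS sgRNAs differed in 457 genes. The shallow library, GATA1TSS-Guide2 replicate 2, is excluded as the whole cause, since 275 genes were called without it. A graded response to the fall of GATA1 may account for the difference: of 194 genes called with eHDAC6 against the 4 control libraries, 92.3% lay further in the eHDAC6 direction with GATA1TSS-Guide2. The highest of the other 9 splits of the 6 libraries gave 89.7%, and 10 splits are too few for a share under 0.05, so this cannot be decided. The prediction was written before the result was seen, and the rule for deciding was tightened afterwards, towards caution. GATA1 was also lower with GATA1TSS-Guide1 than with eHDAC6. Yet eHDAC6 against GATA1TSS called 4 genes without GATA1TSS-Guide2 (edgeR, 820 at an unadjusted p under 0.05). This goes against a response that follows GATA1 evenly over these levels, and does not exclude an uneven response.

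Other groupings of the same libraries were refitted. Splits that exchanged single libraries gave as many genes in 1 of 100 for GATA1TSS against NC (3580, highest other 1466), 1 of 100 for eHDAC6 against NC (4088, highest other 3514) and 1 of 100 for eHDAC6 against GATA1TSS (201, highest other 181). Without the 8 they did so in 2 of 100 for GATA1TSS (1343, highest other 1452) and 1 of 100 for eHDAC6 (195, highest other 44). These splits mix sgRNAs within a group, which adds the differences between sgRNAs to the error and lowers the counts (median of the others 0), so they do not exclude chance differences between sgRNAs. Their highest counts against all controls followed the control subsets: that for eHDAC6 had a group of 6 drawn from the 8 and that for GATA1TSS had none of the 8 in its group of 6, which is a structure of the samples. Exchanging whole sgRNAs gave 15 splits, too few for a share under 0.05: 2 were as large for GATA1TSS (3580, median of the others 899, highest other 4012) and 2 for eHDAC6 (4088, median 316.5, highest other 4518), both highest with NC-Guide1 and NC-Guide2 as the pair. Among the NC sgRNAs 3 of 100 such splits gave as many (1618, highest other 1992), and 19 others called over 100 genes. They take no account of the control subsets, a structure of the samples, so they do not exclude chance either, and a fit of the 12 control libraries alone called 14. Chance cannot be excluded for the number of gene lists called, with 15 of 100 splits for GATA1TSS (10, highest other 12), 18 for eHDAC6 (7, highest other 10), and without the 8 13 (10, highest other 12) and 41 (4, highest other 10). Between the sgRNAs of an element 10 splits are too few for a share under 0.05, with 1 as large for GATA1TSS (457, highest other 5) and 1 for eHDAC6 (2, highest other 0).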

How the results depend on the processing

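The 3 alternatives on the control subsets were chosen after the data had been seen. The p-values measure the spread between replicates of an sgRNA, and the depth of the smallest library limits the thinned fits. In NC-Guide3 and NC-Guide4 the replicates lie in both control subsets, so this spread holds the difference between the subsets. Comparisons without controls share that error. With the subset term, calls rose from 201 to 524 for eHDAC6 against GATA1TSS and from 457 to 877 between the GATA1TSS sgRNAs. Against and among NC, where the term also enters the differences tested, the counts fell. The cause of a change was not tested unless stated. For 147 results on named genes, 1331 of 1433 values under the alternatives fixed in advance kept direction and side of the threshold, 99 no longer passed, 3 newly passed and 0 reversed. With a library or sgRNA left out 4516 of 4684 did so, 164 no longer passed and 4 reversed, and with the 3 alternatives 346 of 441 did so, 84 no longer passed, 4 newly passed and 7 reversed.

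GATA1 with GATA1TSS (-2.74 to -1.63 with a library or sgRNA left out) and HDAC6 with GATA1TSS (0.38 to 0.69) passed under every alternative run. GATA1 with eHDAC6 (-0.55 to -0.47) and the GATA1 difference between the elements (1.12 to 2.23) failed to pass only with counts summed per sgRNA, at -0.51 (edgeR adjusted p = 0.149) and 1.54 (0.153), where 8 sums stand for 24 libraries. HDAC6 with eHDAC6 (-0.39 to -0.28) did not pass with summed counts (-0.34, 0.108), without the 8 (-0.23, 0.0776) or with the subset term (-0.18, 0.343).

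Genes called with GATA1TSS numbered 839 with glmTreat, 632 with summed counts, 1343 without the 8 and 1022 with the subset term, and 1625 (without GATA1TSS-Guide2) to 4136 with libraries or sgRNAs left out. With eHDAC6 they numbered 708, 280, 195 and 109 in the same order, and 1993 (without eHDAC6-Guide2) to 4777, with 2219 without eHDAC6-Guide1 and 2612 without NC-Guide2. Without the 4 neither count moved by over 1.5 times. For eHDAC6 against GATA1TSS the count was 12 with glmTreat, 306 with no filter, 14 with 1 coefficient per element, 0 with summed counts (edgeR, 568 at an unadjusted p under 0.05), 670 with only the groups compared, 394 with DESeq2, 643 without the 8, 524 without the 4 and 524 with the subset term. It ran from 4 (without GATA1TSS-Guide2) to 915 (without GATA1TSS-Guide1), with 34 and 45 without eHDAC6-Guide1 and eHDAC6-Guide2 and 387 without NC-Guide3. Single libraries gave 72 and 101 (GATA1TSS-Guide1 replicates 2 and 3), 119 (GATA1TSS-Guide2 replicate 3), 94 and 75 (eHDAC6-Guide1 replicates 1 and 3), 83, 133 and 131 (eHDAC6-Guide2 replicates 1, 2 and 3), 319 (NC-Guide2 replicate 1) and 361 (NC-Guide3 replicate 1).

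Between the GATA1TSS sgRNAs the count was 106 with glmTreat, 276 thinned, 1087 without the 8, 864 without the 4 and 877 with the subset term. It ran from 178 to 653, with 178 and 194 without GATA1TSS-Guide1 replicates 1 and 3 and 242, 275 and 255 without GATA1TSS-Guide2 replicates 1, 2 and 3. Between the eHDAC6 sgRNAs it was 1 with glmTreat, 73 with only the groups compared, 16 without the 8, 14 without the 4 and 16 with the subset term. It ran from 0 to 2, with 0 without eHDAC6-Guide1 replicate 2 or 3 (edgeR, 414 and 368 at an unadjusted p under 0.05) and 1 without eHDAC6-Guide1 replicate 1, any eHDAC6-Guide2 replicate or GATA1TSS-Guide1. Among the NC sgRNAs it was 14 with only those groups, 2735 with DESeq2, 0 without the 8 (edgeR, 825 at an unadjusted p under 0.05; DESeq2 was not run there), 516 without the 4 and 592 with the subset term. It ran from 224 (without NC-Guide2) to 3249 (NC-Guide3 replicate 1), with 385 without NC-Guide1, 1068 without eHDAC6-Guide1, 974, 698 and 788 without NC-Guide1 replicates 1, 2 and 3, 268 without NC-Guide2 replicate 1, 969 without NC-Guide3 replicate 2, and 2638 and 874 without NC-Guide4 replicates 1 and 2.

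Locus calls with GATA1TSS were 4 in a window of 100 kb, which holds fewer genes, 12 without the 8, 41 without the 4 and 8 with the subset term, and with eHDAC6 3, 4 without the 8 and 1 with the term. They were not rerun with libraries left out. Lists called with GATA1TSS were 3 with an estimated correlation and 17 with fry (10 to 13 with libraries or sgRNAs left out), and with eHDAC6 0 with camera at an estimated correlation (lowest adjusted p 0.0715), 12 with fry, 11 with no filter and 4 without the 8 (5 to 10). The correlation of the responses was 0.156 with no filter, 0.696 and 0.718 at a mean of at least 5 and 20 CPM, 0.496 with summed counts and 0.249 without the 8, and 0.470 (NC-Guide3 replicate 1) to 0.600 with libraries or sgRNAs left out.

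Results that reversed were, without the 8, TF (0.049 with GATA1TSS, 0.047 with eHDAC6) and HBZ with GATA1TSS (0.12), and with the subset term TF (0.12 with GATA1TSS, 0.11 with eHDAC6), HBZ with GATA1TSS (0.13) and ANKRD33 with eHDAC6 (-0.10). For eHDAC6 against GATA1TSS, LOC102723809 (-0.082, range to 1.18 with libraries or sgRNAs left out) and ZBTB1 (-0.034, to 1.39) reversed without GATA1TSS-Guide1, and PGR (-0.18, to 1.01) and AQP1 (-0.026, to 0.87) without GATA1TSS-Guide2, where the comparison rests on the 3 libraries of the other sgRNA.

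Of the genes named with GATA1TSS, leaving out GATA1TSS-Guide2 ended the calls of LDB1 (-0.23), HBE1 (-0.33), HBZ (-0.48), FECH (-0.30), BLVRB (-0.16), STEAP3 (-0.36), TFR2 (-0.24), PLEK (0.74), TYROBP (0.39), COL1A1 (0.22), EGR1 (0.25), PCSK1N (0.40), PIM2 (0.12) and SSX3 (0.20). With eHDAC6, leaving out eHDAC6-Guide1 ended those of ALAS2 (-0.25) and FECH (-0.29). AQP1 between the eHDAC6 sgRNAs was not called without any single eHDAC6 library (-0.74 to -0.63) or without GATA1TSS-Guide1 (-0.68), nor SLC4A1 without eHDAC6-Guide1 replicate 2 (-1.23) or 3 (-1.27).

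The replicate numbers were not taken to pair the samples. Correlations between libraries of different sgRNAs were taken on log2 CPM after subtraction of the mean of each sgRNA. On these residuals same-numbered libraries correlated by a mean r of 0.011 (-0.197 to 0.431), and 9 of 24 correlated best with their own number. In NC-Guide3 and NC-Guide4 the number does go with the control subsets, replicate 1 of both among the 8 and replicates 2 and 3 among the 4. With the number as a replicate block the counts were 3628, 4081, 222, 507, 2 and 1729 in the order above, 11 and 8 lists were called, the correlation was 0.592, and of the calls on named genes only that of PIM2 with GATA1TSS was lost. Summed counts and 1 coefficient per element give no test between sgRNAs, glmTreat none among NC, and lists were not run with DESeq2 or with only the groups compared.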

Other observations

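The tests in this part were all chosen after the results were seen, since no list test was laid down for eHDAC6 against GATA1TSS. With camera, 9 of the 21 lists were called there, and with an estimated correlation 0 were (lowest adjusted p 0.0607; fry called 5). Higher with eHDAC6 were cytosolic ribosomal proteins (6 of 37 genes called, 27 adjusted over the list alone; camera adjusted p = 9.83e-16), erythroid regulators (3 of 14, and 5; 5.66e-06), the integrated stress response (1 of 17, and 1; 8.79e-04) and iron handling (0 of 11, with 4 higher and 1 lower over the list alone; 0.0487). Lower were S phase (1 of 17 lower, and 3; 5.97e-05), G2 and M phase (0 of 20, and 0; 4.17e-04), fibroblast and epithelial markers (1 of 6 higher and 3 lower, and the same over the list alone; 0.0109), glycolysis (1 of 17 lower, and 1; 0.0109) and immediate early genes (1 of 15 lower, and 1 higher and 4 lower; 0.0109).

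ZBTB1 and LOC102723809 on chromosome 14 were lower with GATA1TSS-Guide1 than with GATA1TSS-Guide2. A candidate explanation is binding of GATA1TSS-Guide1 near the starts of both genes, which would repress them locally. The starts lie 35.8 kb apart, on opposite strands with overlapping exons, and the median log2 difference of the 12 other tested genes within 500 kb was -0.02. ZBTB25 and HSPA2, which start within 1 kb of ZBTB1 and of LOC102723809, stood at -0.09 each (edgeR adjusted p = 0.613 and 0.905), which goes against repression that reaches every gene at both starts, although HSPA2 was low at 2.77 CPM. Reads of the overlapping exons may lower both values from a single repressed gene, so the explanation stays open, and the sgRNA sequences were not used here.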
